A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

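The deposited values are log2 ratios that the authors had already normalized; the deposited labels give the numerator and the dye of each array, and every ratio was oriented so that the first-named strain or condition is above the line. Per the labels, cells of the strain CML128 (MATa) and its derivatives, a deletion of HCM1, an HA-tagged HCM1 and HA-tagged HCM1 under a tet promoter that doxycycline represses, grew in YPD at 30 °C, and total RNA was labelled indirectly with Cy5 and Cy3. The normalization method and the software used upstream are not given in the sources used here. Array medians lay between -0.05 and 0.09, and each array was centred on its median before use.

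The columns were read as log2 because 2 raised to each value fell on a grid of 0.001 for 100% of values in 11 columns and for 39.7% in the first column of the tagged strain. Read as natural logarithms, at most 29.2% fell on it in any column, and 23.2% in that first column. The grid thus says little for that column on its own. The arrays held values for 2520 to 6174 ORFs, and a comparison used ORFs with a value on both arrays: 5161 in the deletion, 3955 and 4307 in the 2 tet comparisons, 2495 after 4 h and 2312 after 10 h of doxycycline. Of the ORFs, 5675 matched the gene table used for names, neighbours and coding length and 499 did not; 97.1% of coding lengths were multiples of 3. No coordinates are given, as the sources name no genome build.

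The value of a gene in a comparison is the mean log2 ratio of the 2 dye-swapped arrays, which cancels a dye effect, with the SD of the 2 arrays. The tagged strain over wild type is the exception, because its 2 columns mirror each other; only the first column was used, a choice made after the data were seen. The plan fixed before the data were examined averaged the 2 columns, and that alternative is given beside each count it changes. Each pair of arrays counted as 1 replicate, on the series text's statement of a dye swap for each RNA sample; separate RNA for Exp 1 and Exp 2 is not ruled out by the labels. Genes were tested with limma (lmFit and eBayes, R 4.3.3, limma 3.58.1) on the 6 comparison values, with the residual taken from the control comparisons (3 degrees of freedom, 2 when a control was tested), and p was adjusted by Benjamini-Hochberg within a comparison. A gene without values in enough control comparisons could not be tested. The test assumes that control ratios have no true change, so that any effect of the tag or doxycycline widens the residual.

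The 30 gene lists were fixed by name before the data were examined, and 29 had measured members. Of 907 list genes, 15 had no ORF in the table and 8 are encoded in mitochondria. Lists were tested with cameraPR at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over all lists of the 3 Hcm1 comparisons together, and in the same way over the 3 controls. Camera with a correlation estimated from the data and fry were run as alternatives. That correlation came from the control comparisons alone, where a shift shared by a list, as under doxycycline, counts as correlation. With it no list passed in any comparison, so it cannot set lists apart. Percentiles come from 10000 random lists of the same size, which were not matched for expression.

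Named genes follow a rule fixed before the data were examined: HCM1 first; the 10 highest and 10 lowest per Hcm1 comparison, those that passed first and then those with the larger smaller-of-2-arrays size; 3 and 3 per control; genes that passed in both tet comparisons, of which there were none; the 4 members of each list furthest from 0, of which the text names those needed; and the neighbours of HCM1 and the auxotrophic markers. The text also gives counts of genes at least 2-fold changed on both arrays, which use no test.

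In simulated data, 50 genes each were changed by a log2 of 5, 3, 2 and 1 in the same run. The test recovered 48, 45, 32 and 5 of them in the deletion, 50, 46, 35 and 9 in tet over own promoter and 50, 46, 31 and 2 in tet without over with doxycycline. So many changed genes ease the Benjamini-Hochberg threshold, so these shares do not carry over to data with few changes. A lone changed gene of median standard error needed a log2 ratio of 3.70, 3.44 and 3.53 in these comparisons, in the same order. False calls numbered 7, 7 and 5 over each whole run, with all sizes together. A list shifted by 0.5 reached an adjusted p of 1.05e-05, 3.24e-08 and 0.00198, and 0, 0 and 1 of the lists left unshifted passed as well. Simulated genes varied independently, so this run cannot show how often lists of genes that vary together pass without a shift. Alternatives covered scaling, robust fits, the replicate unit, array subsets, fold thresholds, leaving out comparisons, coding length, chromosome IX and the list test. Raw intensities, background and spot quality were not used here.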

Results

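The data were log2 ratios from 12 2-colour arrays of budding yeast, 2 dye-swapped arrays for each of 6 comparisons of strains with altered levels of the forkhead transcription factor Hcm1. In 3 comparisons the level of HCM1 differed by design: a deletion strain over wild type, a strain with HCM1 under a tet promoter over the tagged strain with its own promoter, and the tet strain without doxycycline over the same strain after 10 h of doxycycline. The other 3 were controls: the tagged strain over the untagged wild type, and the tagged strain with doxycycline for 4 h and for 10 h over the tagged strain without it. The series text gives a dye swap for each RNA sample, so the 2 arrays of a comparison were treated as 1 RNA pair with no independent replicates, though their labels, Exp 1 and Exp 2, do not settle this. Every SD below is a spread over 2 arrays (n = 2), taken as technical. Of 6174 ORFs, 1592 had a value on all 12 arrays.

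Within a comparison the 2 arrays correlated with a Pearson r of 0.56 for the deletion, 0.64 for the tet promoter over the own promoter, 0.76 for the tet strain without over with doxycycline, 0.53 for 4 h and 0.71 for 10 h of doxycycline. The 2 columns of the tagged strain over wild type were mirror images of each other, with r = -0.999 and an SD of their sum of 0.0144, so that comparison rests on 1 array. The first column was used with the direction its label gives; the label of the second gives the opposite direction, and which sign is right was not settled.

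**Figure D1:**
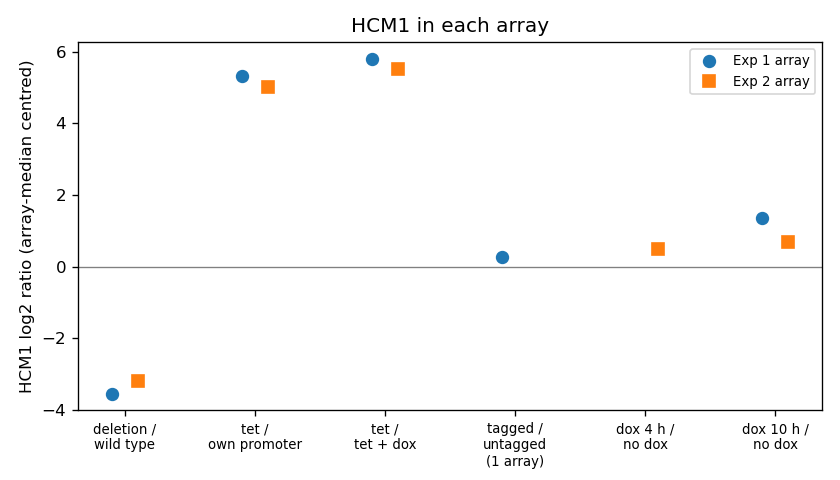
HCM1 log2 ratio on each array, by comparison. Each point is 1 array, with arrays of the same dye-swapped pair side by side.

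In the deletion strain, the HCM1 signal itself was lower by 3.36 ± 0.26 (log2, -3.36, 10.3-fold, n = 2 arrays). RPN1, a proteasome subunit gene, was lower at -2.53 ± 0.25, and NUP188, a nuclear pore gene, at -2.07 ± 0.23. The other 7 of the 10 lowest genes all lie on chromosome IX: KGD1 (-2.60 ± 0.55), MET18 (-2.12 ± 0.06), PFK26 (-1.65 ± 0.10), HIS5 (-1.65 ± 0.15), TPM2 (-1.54 ± 0.05), SNP1 (-1.54 ± 0.07) and FMC1 (-1.51 ± 0.03). Higher values were smaller. ARG3, of arginine synthesis, stood at 1.03 ± 0.14, and MMP1 (0.80 ± 0.21), SAM3 (0.79 ± 0.24) and MHT1 (0.65 ± 0.06), of S-methylmethionine and S-adenosylmethionine use, were higher, as were the zinc transporter gene ZRT1 (0.77 ± 0.20), the serine deaminase gene CHA1 (0.71 ± 0.16), PUN1 (0.59), YIR043C (0.72 ± 0.06), YAR069C (0.70 ± 0.08) and YIR044C (0.63 ± 0.01). Of these, HCM1, KGD1, PFK26, MMP1, SAM3, CHA1, PUN1 and YIR043C could be tested and did not pass; the others had too few control values for a test. Nor did the list of sulphur and methionine genes pass, with a median of 0.13 and with MET3 (-0.83 ± 0.07) and MET28 (-0.83 ± 0.16) lower. MET28 lies on chromosome IX.

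Kinetochore and spindle genes, the class for which Hcm1 is best known, had a median of -0.14 in the deletion, with 34 of 50 lower, and this median lay at percentile 1.5 of random lists of the same size. DSN1 (-1.14 ± 0.32), TUB2 (-1.08 ± 0.05) and MTW1 (-0.91 ± 0.23) were among the members furthest from 0; DSN1 lies on chromosome IX. The list did not pass the test (cameraPR, Benjamini-Hochberg adjusted p = 0.174). The S phase regulator list, which holds the transcription factor genes SWI4 (-0.79 ± 0.34) and FKH1 (-0.62 ± 0.10), had a median of -0.13 (adjusted p = 0.303). FKH1 lies on chromosome IX as well, whose genes had a median of -0.92 in the deletion.

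Ergosterol synthesis genes rose in the deletion, with 22 of 25 higher and a median of 0.38 (cameraPR, adjusted p = 1.25e-05, and adjusted p = 0.948 with an estimated correlation). ERG2 (0.71 ± 0.67), ERG3 (0.66 ± 0.44), ERG11 (0.62 ± 0.22) and ERG28 (0.58 ± 0.33) led the list. Genes of the amino acid starvation response under Gcn4 fell as a list, with a median of -0.07 and a mean of -0.16 (cameraPR, adjusted p = 0.0201, and adjusted p = 0.948 with an estimated correlation). Its members went both ways: HIS5 (-1.65 ± 0.15), LYS12 (-1.25 ± 0.02) and SNZ1 (-1.23 ± 0.11) were lower while ARG3 was higher. The 2 arrays put its median at 0.11 and -0.28, and without chromosome IX genes its adjusted p was 0.0516. Ribosomal protein genes were higher in 96 of 126 cases, with a median of 0.28, and missed the threshold (adjusted p = 0.127).

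Chromosome IX as a whole stood apart in the deletion. Of 193 measured genes on it, 187 were lower, with a median of -0.92 (1.89-fold) that was -0.86 on the first array and -0.87 on the second. Quartiles were -1.15 and -0.64, the left arm had a median of -0.94 over 155 genes and the right arm -0.81 over 38. The medians of all other chromosomes lay between -0.23 (VI) and 0.13 (III). In the other comparisons the median of chromosome IX was -0.16, -0.22, -0.02, -0.21 and -0.25, in the order tet over own promoter, tet without over with doxycycline, tagged over untagged, and 4 h and 10 h of doxycycline.

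**Figure D2:**
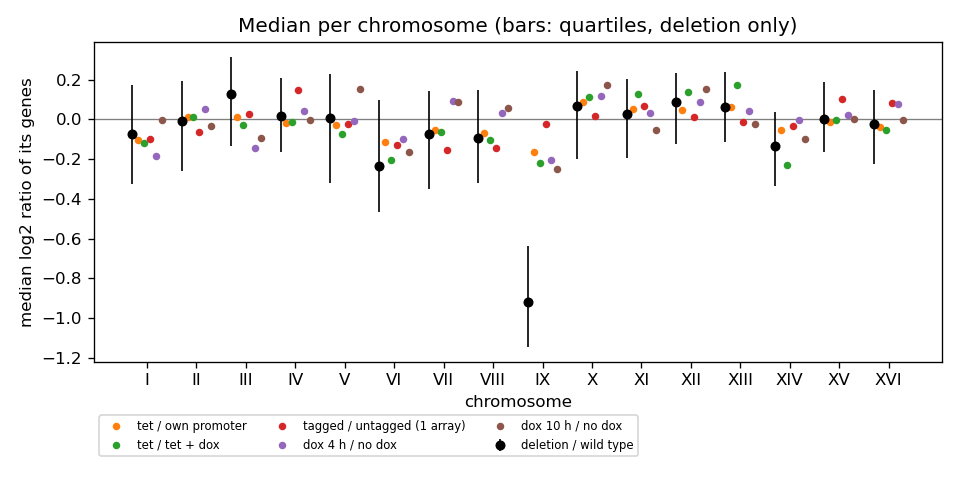
Median log2 ratio of the genes of each chromosome in the 6 comparisons.

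Across all genes, 0 of 2538 tested passed in the deletion (limma, Benjamini-Hochberg adjusted p below 0.05), and 26 had an unadjusted p below 0.05; HCM1 had an adjusted p of 1.00. At least a 2-fold decrease on both arrays was seen for 79 genes, 51 of them on chromosome IX and 28 elsewhere, and an increase of that size for 0. The residual of the test came from the 3 control comparisons, each a single RNA pair, and the share of chromosome IX genes limits what the 79 can say about Hcm1.

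With HCM1 under the tet promoter, its own signal was higher than under its own promoter by 5.17 ± 0.20 (35.9-fold, n = 2 arrays), and higher by 5.65 ± 0.20 (50.2-fold) than in the same strain after 10 h of doxycycline. In the comparison over the own promoter, the other 9 of the 10 highest genes included HSP26 (2.97 ± 0.07) and SSA4 (1.87 ± 0.07), which encode chaperones, HSP30 (2.58 ± 0.08), which encodes a plasma membrane stress protein, YGP1 (1.84 ± 0.05) and SPI1 (1.53 ± 0.21), which encode cell wall proteins induced near the end of growth, and YRO2 (2.22 ± 0.09). WSC4 (2.29 ± 0.39), a stress sensor gene of the CLB2 cell cycle cluster, PRY1 (2.02 ± 0.43) and BNA4 (1.72 ± 0.13), of NAD synthesis, were the others. WSC4 and SSA4 could not be tested, the others did not pass, and neither did the general stress list, with a median of 0.15 (cameraPR, adjusted p = 0.303). Among the lowest were the acid phosphatase genes PHO12 (-1.79 ± 0.15) and PHO11 (-1.73 ± 0.21), the pheromone-regulated gene PRM5 (-1.67 ± 0.12), the histone chaperone gene SPT16 (-1.49 ± 0.14) and MDS3 (-1.36 ± 0.01). YLR162W (-1.94 ± 0.17), YLR122C (-1.59 ± 0.17), YLR012C (-1.38 ± 0.30), YJR029W (-1.36 ± 0.21) and YHL049C (-1.29 ± 0.13), which have no standard name, were lower too. PHO12, SPT16, MDS3 and YHL049C could not be tested, and the others did not pass.

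Respiratory chain and ATP synthase genes rose with the tet promoter, with 31 of 33 higher and a median of 0.57 (cameraPR, adjusted p = 4.43e-09, and adjusted p = 0.948 with an estimated correlation). QCR10 (1.40 ± 0.10), ATP5 (1.23 ± 0.38), ATP16 (1.06 ± 0.34) and ATP7 (0.97 ± 0.21) led; these are short genes, and with the trend on coding length removed the median was 0.40 (adjusted p = 1.22e-07). Glycolysis and fermentation genes fell, with 25 of 26 lower and a median of -0.37 (cameraPR, adjusted p = 2.95e-04, and adjusted p = 0.948 with an estimated correlation). GPP1 (-1.04 ± 0.23), HXT2 (-0.75 ± 0.14), HXK2 (-0.74 ± 0.31) and GPD2 (-0.66 ± 0.14) were lowest, and the 2 arrays put the list at -0.04 and -0.69. Phosphate starvation genes fell as well, with 11 of 14 lower and a median of -0.44 (cameraPR, adjusted p = 2.95e-04, and adjusted p = 0.948 with an estimated correlation); next to PHO12 and PHO11 were PHO5 (-0.94 ± 0.03) and, the other way, PHM8 (0.90 ± 0.45).

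Kinetochore and spindle genes had a median of 0.09 with the tet promoter, 23 of 37 being higher (cameraPR, adjusted p = 0.578). NNF1 (0.92 ± 0.27), CTF3 (0.76 ± 0.29) and DAD4 (0.67 ± 0.57) were higher and MTW1 (-0.90 ± 0.19) was lower. The test pointed down although the median was above 0. The mitotic cyclin gene CLB1 (1.52 ± 0.46) and NDD1 (0.60 ± 0.24), the coactivator gene of the CLB2 cluster, were higher, in lists with medians of 0.14 (adjusted p = 0.417) and -0.10 (adjusted p = 0.574).

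No gene passed over the own promoter: 0 of 2435 (limma, Benjamini-Hochberg adjusted p below 0.05), with 113 at an unadjusted p below 0.05, and HCM1 at an adjusted p of 0.0560. On both arrays 46 genes were at least 2-fold higher and 21 at least 2-fold lower. Coding length and log2 ratio were related with a Spearman coefficient of -0.21 in this comparison, with -0.26 on the first array and -0.09 on the second.

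HCM1 rose in the tet strain without doxycycline over the same strain after 10 h of doxycycline, by 5.65 ± 0.20 (limma, Benjamini-Hochberg adjusted p = 0.0445), a call that was lost with the mirrored columns averaged as first planned. HSP26 (3.74 ± 0.43) and SSA4 (2.30 ± 0.22) were again high, as were BNA4 (2.29 ± 0.02), WSC4 (2.04 ± 0.03) and PRY1 (2.19 ± 0.35). PUT1 (2.47 ± 0.50), of proline use, GDH2 (2.24 ± 0.24), of glutamate breakdown, YKR075C (2.25 ± 0.02) and YPL185W (1.94 ± 0.03) were among the 10 highest here only. The lowest were SPT16 (-3.69 ± 0.74), RPN1 (-3.53 ± 0.28), the vacuolar transporter gene BPT1 (-3.44 ± 0.49), the mitochondrial folate enzyme gene MIS1 (-3.39 ± 0.57), the membrane contact gene TCB3 (-3.24 ± 0.74), NUP188 (-2.78 ± 0.12), KGD1 (-2.75 ± 0.24), YDL172C (-2.69 ± 0.41), YLR339C (-2.66 ± 0.65) and the corepressor gene CYC8 (-2.61 ± 0.48). Each of these lowest genes was lower in the deletion as well, from -2.60 (KGD1) to -1.37 (YDL172C). Those of them measured after 4 h of doxycycline in the tagged strain were lower there too, from -2.42 (BPT1) to -0.58 (YLR339C). SSA4, WSC4, RPN1, SPT16, BPT1, MIS1, NUP188 and YDL172C could not be tested, and the other genes besides HCM1 did not pass.

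General stress genes rose without doxycycline, with 24 of 29 higher and a median of 0.64 (cameraPR, adjusted p = 0.0302, and adjusted p = 0.948 with an estimated correlation), HXK1 (1.96 ± 0.13) and HSP30 (1.86 ± 0.02) following the chaperone genes. The denominator had 10 h of doxycycline, and general stress genes fell after 10 h of doxycycline in the tagged strain, HSP26 to -3.14 ± 0.08. The rise can thus not be assigned to Hcm1 rather than to doxycycline. This list did not pass when the mirrored columns of the tagged strain were averaged as first planned (adjusted p = 0.389), or with the dye effect taken from the tagged array (adjusted p = 0.0559). NAD and sirtuin genes rose too, with 12 of 17 higher and a median of 0.23 (cameraPR, adjusted p = 0.0123, and adjusted p = 0.948 with an estimated correlation). Its highest members were the biosynthesis genes BNA4 (2.29 ± 0.02), BNA2 (1.45 ± 0.16), BNA5 (1.37 ± 0.13) and BNA1 (1.16 ± 0.00). With the tet promoter over the own promoter, BNA4 (1.72 ± 0.13), BNA1 (1.03 ± 0.04), BNA5 (0.83 ± 0.04) and the transporter gene TNA1 (0.69 ± 0.02) were higher with a list median of 0.19 (adjusted p = 0.0582). Ergosterol genes fell, with 21 of 25 lower and a median of -0.50 (cameraPR, adjusted p = 0.00177, and adjusted p = 0.948 with an estimated correlation); MVD1 (-1.05 ± 0.21), NCP1 (-1.05 ± 0.19), ERG25 (-1.02 ± 0.19) and HMG1 (-0.86 ± 0.17) were lowest. The list had risen in the deletion, but it also rose, by 0.43, after 10 h of doxycycline in the tagged strain, and the denominator here had 10 h of doxycycline.

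Ribosomal protein genes fell without doxycycline, with 92 of 122 lower and a median of -0.14 (cameraPR, adjusted p = 0.0123, and adjusted p = 0.959 with an estimated correlation), but the 2 arrays put the median at 0.14 and -0.44. RPS14A (-1.74 ± 0.39), RPS1A (-1.28 ± 0.48), RPL7B (-1.08 ± 0.36) and RPL27A (-0.93 ± 0.31) were lowest. Gcn4 targets fell with a median of -0.12, 25 of 38 being lower (cameraPR, adjusted p = 0.0123, and adjusted p = 0.948 with an estimated correlation), among them MET6 (-1.69 ± 0.05), LYS2 (-1.18 ± 0.05), LYS1 (-0.96 ± 0.04) and ARG8 (-0.96 ± 0.30). Both lists rose after 10 h of doxycycline in the tagged strain, and the denominator here had 10 h of doxycycline. Kinetochore and spindle genes had a median of 0.22, with 29 of 45 higher, while the test pointed down (cameraPR, adjusted p = 0.605). NNF1 (1.48 ± 0.36), NSL1 (1.16 ± 0.44) and SPC98 (1.15 ± 0.12) were higher and TUB2 (-1.20 ± 0.02) was lower, as it was in the deletion (-1.08), over the own promoter (-0.43) and after 4 h (-0.88) and 10 h (-0.84) of doxycycline in the tagged strain.

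HCM1 was the only gene of 2480 that passed (limma, Benjamini-Hochberg adjusted p below 0.05), and 233 had an unadjusted p below 0.05. The count was 0 when the mirrored columns of the tagged strain were averaged as first planned; using only the first of them was chosen after the data were seen. It was also 0 with values as deposited, a robust fit, no tagged control, the dye-corrected tagged array or length removed. It was 95 without the 10 h control and 149 with the values corrected for that control. On both arrays 138 genes were at least 2-fold higher and 93 at least 2-fold lower.

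**Figure D3:**
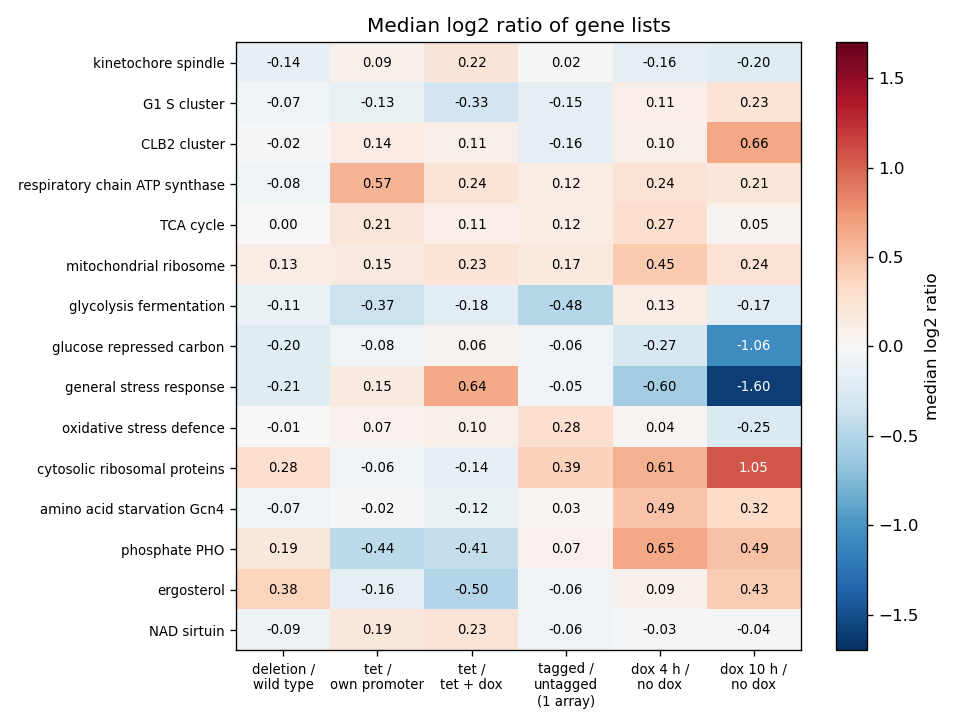
Median log2 ratio of each gene list in the 6 comparisons.

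The medians that follow are of lists that did not pass in the comparison given, though some passed in another, as described above. Where 3 are given, the order is deletion, tet over own promoter, tet without over with doxycycline. Among cell cycle lists, the G1/S cluster stood at -0.07, -0.13 and -0.33, histone genes at 0.25, 0.17 and 0.39, the CLB2 cluster at -0.02, 0.14 and 0.11 and the M/G1 cluster at 0.02, 0.02 and -0.17. S phase regulators were at -0.18 in the last of these, where too few members were tested. In the M/G1 cluster the replication gene MCM3 was at -1.43 ± 0.43 in the deletion and -1.85 ± 0.57 without doxycycline. Among mitochondrial lists, respiratory chain genes stood at -0.08 in the deletion and 0.24 without doxycycline, TCA cycle genes at 0.00, 0.21 and 0.11 and mitochondrial ribosome genes at 0.13, 0.15 and 0.23.

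Oxidative stress defence genes had medians of -0.01, 0.07 and 0.10, general stress genes -0.21 in the deletion, the iron regulon 0.10, -0.06 and 0.04, and glucose-repressed genes -0.20, -0.08 and 0.06. Glycolysis genes stood at -0.11 in the deletion and -0.18 without doxycycline. Ribosome biogenesis genes had -0.10, -0.06 and 0.07, ribosomal protein genes -0.06 over the own promoter, Gcn4 targets -0.02 there, and sulphur and methionine genes -0.17 and -0.14 in the 2 tet comparisons. Phosphate genes were at 0.19 in the deletion and -0.41 without doxycycline, ergosterol genes at -0.16 over the own promoter, and NAD genes at -0.09 in the deletion. Pleiotropic drug resistance genes had 0.24, -0.21 and -0.23 and cell wall integrity genes 0.18, 0.24 and -0.01.

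Pheromone response genes stood at 0.20, 0.03 and 0.20, with PRM5 (-1.84 ± 0.29) and PRM3 (1.49 ± 0.17) going apart without doxycycline. Markers of other cell types were measured on few genes and not tested: the a-cell list had a median of -0.14 in the deletion and -0.44 without doxycycline. Over the own promoter its members STE2, STE6 and BAR1 were at -0.48, -0.37 and 0.03. Of the alpha-cell genes, SAG1 was at -0.17, 0.00 and -0.12, and MF(ALPHA)2 at -0.56 ± 0.09 in the deletion. Sporulation and diploid markers had 0.10, 0.32 and 0.22. The neighbours of HCM1, too few to test as a list, had a median of 0.58 in the deletion: RAD18 (0.71 ± 0.33), YCR064C (0.67 ± 0.41), TVS1 (0.49 ± 0.36) and BUD31 (0.27 ± 0.39). TVS1 did not pass the test and the other 3 were not tested. Over the own promoter they were at 0.17 (RAD18), 0.05 (TVS1) and -0.04 (BUD31), and without doxycycline at 0.63, -0.29 and -0.37. Of the auxotrophic markers, HIS4 was at -0.84 ± 0.03 in the deletion, LEU2 at 0.38, URA3 at -0.20 and TRP1 at 0.07; without doxycycline URA3 was at -0.77 ± 0.29.

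Of 71 list tests in the Hcm1 comparisons (cameraPR, Benjamini-Hochberg over all 71), 10 passed, 4 up and 6 down, and 0 passed with an estimated correlation. With that correlation no list passed in the controls either, not even ribosomal protein genes after 10 h of doxycycline, all of which were higher. It thus cannot set lists apart. In 11 of the 71 the median and the test pointed opposite ways, none of them among the 10.

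The 2 tet comparisons both have the tet strain without doxycycline above the line, so some sharing follows from the design. Of 3841 genes measured on all 4 arrays, 46 were at least 2-fold higher over the own promoter and 126 without doxycycline, and 40 were in both, HCM1 and 39 others. At least 2-fold lower were 21 and 79, with 15 in both. Simulated unchanged groups with normal spread that share 1 RNA had 6.96 and 7.04 in both. HCM1, HSP26, SSA4, WSC4, BNA4 and PRY1 were among the shared high genes and SPT16 among the low ones. Over 3841 genes the 2 comparisons had r = 0.78 (Spearman 0.72, covariance 0.191), against 0.42 and a covariance of 0.122 in the same simulated groups, since the labels do not rule out that both used the same tet RNA. The tested contrast between them called no gene (limma, 0 of 2407, 3 at an unadjusted p below 0.05). Its power was not simulated, and it does not show that the comparisons were alike: YKR075C, at -0.85 and 2.25, did not pass.

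Across genes the deletion and the tet comparisons had no negative correlation. Its r was 0.35 with tet over own promoter (Spearman 0.44) and 0.40 with tet without over with doxycycline (Spearman 0.40), both positive, where opposite effects of losing and gaining Hcm1 would give negative values. Between arrays of like dye order the values were 0.44 and 0.31 for the first and 0.42 and 0.43 for the second. Between arrays of unlike dye order they were 0.11 and 0.20 for the first and 0.0954 and 0.38 for the second. A dye effect of each gene would raise the former and lower the latter, so neither is free of it. The genes RPN1, NUP188 and KGD1 were among the 10 lowest both in the deletion and without doxycycline. At least 2-fold lower in both of these were 26 genes, against 1.63 if independent, and HCM1 was the only gene 2-fold lower in the deletion and 2-fold higher in a tet comparison.

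**Figure D4:**
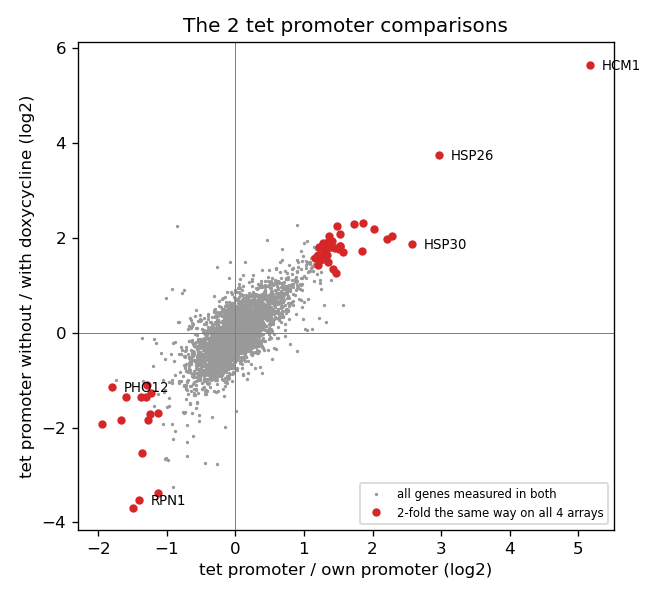
Mean log2 ratio of each gene in tet over own promoter against tet without over with doxycycline.

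In the control array of the tagged strain over untagged wild type, HCM1 stood at 0.27 in the first column and at -0.27 in the second. All values that follow are from the first column, with its dye effect not cancelled, and the second gives nearly all of them with the opposite sign, so that the direction of this comparison stays undecided. RTS2 (3.42) was highest, followed by TOS6 (0.85) and ESS1 (0.84), and YLR162W (-2.14), YGL088W (-2.10) and YLR012C (-1.69) were lowest, on 1 array each. Histone genes had a median of 0.45, 9 of 9 being higher (cameraPR, adjusted p = 0.00864), and ribosomal protein genes 0.39, 112 of 116 being higher (adjusted p = 1.51e-04). Glycolysis genes had a median of -0.48 (cameraPR, adjusted p = 1.05e-06) and glucose-repressed genes one of -0.06 (adjusted p = 0.0304), with MLS1 (-1.46) and HXT7 (-0.88) among the lowest; these 4 lists had an adjusted p = 0.972 with an estimated correlation. Kinetochore and spindle genes had a median of 0.02. Of 1644 genes 0 passed (limma, adjusted p below 0.05), with 2 at an unadjusted p below 0.05. Length related to the ratio with a Spearman coefficient of -0.55 in this column.

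After 4 h of doxycycline in the tagged strain, the dehydration stress genes GRE1 (-3.78 ± 0.09) and SIP18 (-3.35 ± 0.15) were lowest, with YBR116C (-2.60 ± 0.48). URA1 (1.94 ± 0.04), ARG1 (1.91 ± 0.02) and GDH1 (1.89 ± 0.02), of pyrimidine, arginine and glutamate synthesis, were highest. Ribosomal protein genes rose with a median of 0.61, 103 of 106 being higher (cameraPR, adjusted p = 2.85e-09), Gcn4 targets by 0.49 (adjusted p = 0.00339), mitochondrial ribosome genes by 0.45 (adjusted p = 0.00576) and the iron regulon by 0.56 (adjusted p = 0.00666); each had an adjusted p = 0.972 with an estimated correlation. FET3 (1.58 ± 0.01) and SIT1 (1.47 ± 0.26) were among the highest of the iron regulon. General stress genes had a median of -0.60, 26 of 35 being lower (cameraPR, adjusted p = 0.235). HCM1 was measured on the second array only, at 0.50. Of 1644 genes 0 passed (limma, adjusted p below 0.05), with 42 at an unadjusted p below 0.05.

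After 10 h of doxycycline in the tagged strain, FDH1 (-3.48 ± 0.24), a formate dehydrogenase gene, the Ty element ORF YMR051C (-2.99 ± 0.00) and BAG7 (-2.98 ± 0.05), of actin and cell wall signalling, fell, and UTR2 (2.49 ± 0.29), a cell wall enzyme gene, and MUP1 (2.39 ± 0.17), a methionine transporter gene, rose. FAA3 passed with 3.30 ± 4.01, but its 2 arrays gave 6.14 and 0.47. General stress genes fell as a list, with a median of -1.60 and 35 of 35 below 0 (cameraPR, adjusted p = 9.94e-18, and adjusted p = 0.647 with an estimated correlation); GRE1 (-3.38 ± 0.15), HSP26 (-3.14 ± 0.08), NQM1 (-3.10 ± 0.02) and ALD3 (-3.01 ± 0.11) were lowest. Ribosomal protein genes rose as a list, with a median of 1.05 and 117 of 117 above 0 (cameraPR, adjusted p = 2.24e-24, and adjusted p = 0.972 with an estimated correlation), RPS22A (1.83 ± 0.35) first, and 73 passed with p adjusted over the list alone.

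Sulphur and methionine genes rose after 10 h with a median of 0.99 (cameraPR, adjusted p = 8.35e-04, and adjusted p = 0.972 with an estimated correlation), with SAM1 (2.22 ± 0.63) and CYS3 (1.72 ± 0.32), and glucose-repressed genes fell with -1.06 (adjusted p = 4.91e-05, and likewise adjusted p = 0.972 with an estimated correlation), with ACS1 (-3.12 ± 0.39) and ADY2 (-2.49 ± 0.16) lowest. Smaller rises were those of the CLB2 cluster (0.66, adjusted p = 0.0322), ergosterol genes (0.43, adjusted p = 0.0255), led by ERG5 (1.84 ± 0.08), and Gcn4 targets (0.32, adjusted p = 0.0177). These 3 lists had an adjusted p = 0.972 with an estimated correlation. HCM1 was higher by 1.02 ± 0.49 (2.03-fold) and not tested, and kinetochore and spindle genes had a median of -0.20, and NUD1 fell, at -1.36 ± 0.20. In total 178 of 1644 genes passed, 87 up and 91 down (limma, Benjamini-Hochberg adjusted p below 0.05), a count that was 10 with the mirrored columns averaged as first planned and 102 with the dye effect taken from the tagged array. The 2 doxycycline times correlated with r = 0.61, with 10 genes 2-fold higher and 19 2-fold lower in both. They share the tagged strain below the line, and simulated unchanged groups that share 1 RNA had r = 0.34, with 1.85 and 1.78 genes in both.

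The medians of the other lists in the control comparisons, in the order tagged over untagged (first column), 4 h and 10 h, were as follows. G1/S cluster genes stood at -0.15, 0.11 and 0.23, M/G1 genes at -0.12, 0.27 and 0.39, respiratory chain genes at 0.12, 0.24 and 0.21, TCA cycle genes at 0.12, 0.27 and 0.05, oxidative stress genes at 0.28, 0.04 and -0.25, and phosphate genes at 0.07, 0.65 and 0.49. Ribosome biogenesis genes had -0.03, 0.32 and 0.51, cell wall integrity genes -0.18, 0.06 and 0.25 and NAD genes -0.06, -0.03 and -0.04. Pheromone response genes stood at 0.00, 0.11 and 0.10 and S phase regulators at 0.35, -0.25 and 0.47, both untested. Of lists that passed in another control, or are given above in part, tagged over untagged and 4 h had medians of -0.16 and 0.10 for the CLB2 cluster, 0.07 and 0.30 for sulphur genes and -0.06 and 0.09 for ergosterol genes. Tagged over untagged and 10 h had 0.17 and 0.24 for mitochondrial ribosome genes and -0.14 and 0.37 for the iron regulon. At 4 h and 10 h histone genes had 0.25 and 0.23 and glycolysis genes 0.13 and -0.17. Tagged over untagged had -0.05 for general stress genes, 0.03 for Gcn4 targets and -0.42 for drug resistance genes, and 4 h had -0.16 for kinetochore and spindle genes, -0.27 for glucose-repressed genes, -0.31 for drug resistance genes and -0.57 for sporulation markers. None of these passed. Of 63 list tests in the controls, 5 had a median and a test that pointed opposite ways, none of them among those that passed.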

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

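All tests that weigh an explanation in this part were chosen only after the results were seen. Differences between the 2 doxycycline times and between the 2 tet comparisons stood out for single genes. After 10 h against 4 h of doxycycline in the tagged strain, UTR2 differed by 1.94 (limma, adjusted p = 0.00293), MUP1 by 1.85 (adjusted p = 0.00572), FAA3 by 3.34 (adjusted p = 3.87e-09), the Ty ORF YMR051C by -2.15 (adjusted p = 7.47e-04) and BAG7 by -2.88 (adjusted p = 7.28e-07). In total 47 of 1644 genes differed, 11 up and 36 down, with 1 residual degree of freedom, which rests on the tagged array alone. FAA3 stood out by sign too, at 3.30 after 10 h and -0.04 after 4 h, but the 4 h value is near 0 and no opposite change was tested; its 2 arrays at 10 h gave 6.14 and 0.47. YKR075C was at 2.25 without over with doxycycline and at -0.85 over the own promoter; that gene did not pass a test of the difference.

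Of 193 chromosome IX genes 187 were lower in the deletion, with a median of -0.92, while YIR043C (0.72) and YIR044C (0.63) of that chromosome were among the highest genes. Spot position on the array is argued against, since the median of the same genes reached at most 0.25 in size in the other 5 comparisons, against the 0.92 seen here. An extra copy in the wild type strain stayed open: the tagged strain over that wild type was at -0.022, but the tagged strain derives from it and can carry the copy too. A lower copy number of chromosome IX in the deletion RNA than in the wild type RNA remained open, and the values went with it. Both arms were shifted on both arrays, the arm and array closest to 0 being at -0.69, and no other chromosome went beyond 0.233. An extra copy in wild type would itself give this. The ratios cannot tell it from a loss of some, but not all, copies in the deletion strain. Loss of an only copy is argued against by the median of -0.92, as the deleted HCM1 itself stood at -3.36. The labels give the mating type MATa, and the number of copies was not measured. Whether loss of Hcm1 led to the shift was not tested, as the labels name 1 deletion strain.

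The 39 ORFs besides HCM1 that were 2-fold higher on all 4 tet arrays had medians of 1.37 and 1.80 in the tet comparisons, and deletion quartiles of 0.02 and 0.29. The 6 lowest in the deletion were SSA4 (-0.80), WSC4 (-0.62), HSP26 (-0.55), GDH2 (-0.40), BNA4 (-0.23) and YGP1 (-0.22), named here after their values were seen. They are included in the values that follow, but differ from the rest. The same labelled material on many spots stayed open: in the comparisons that played no part in choosing them, their spread was 0.301 of that of all genes in the deletion and 0.333 after 10 h of doxycycline, but 0.614 in the tagged array and 0.760 after 4 h, above the 0.5 set as the bound. Print plates rich in ORFs of chromosomes IV, XV and XVI remained open too, as 64.1% of them (25 of 39) lie there against 30.5% of measured ORFs, and 13 of 39 have no standard name (33.3% against 9.27%). The chromosomes were named after the results were seen, so the excess on them cannot decide it. Genes that follow the level of Hcm1 cannot be told apart from these explanations by the deletion median of 0.25. Any of them silent in wild type could not fall further, and which of them were silent was not examined. The same ORFs had medians of 0.31 in the first tagged column, 0.31 after 4 h and 0.41 after 10 h of doxycycline. A median above 0 was thus not particular to the deletion.

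Low stress genes and high ribosomal protein genes after 10 h of doxycycline formed the third pattern. Doxycycline acting alike in both strains stayed open: the tet comparison, with doxycycline below the line, had stress genes at 0.64, near the 0.80 set as the bound, and ribosomal protein genes at -0.14, a smaller shift than the rise of 1.05, and the level of Hcm1 differed there too. Over 2207 genes the 2 comparisons had r = 0.03, where an effect alike in both strains alone would give a negative value. This does not decide it, since a shared positive component could mask it: the deletion correlated with both, at 0.40 and 0.36. Of genes 2-fold changed in both, 10 were higher in the tet comparison and lower after 10 h, and 0 the reverse. Another 10 were lower in both, and 0 were higher in both. One stressed reference RNA of the tagged strain stayed open as well. In tet over own promoter, which has that strain below the line, stress genes had a median of 0.15, which goes against it unless the tet strain had stress changes of its own. After 4 h, with the same strain below the line, stress genes were at -0.60 and ribosomal protein genes at 0.61, which goes with it. A difference in growth stage was not tested, nor was any biological explanation that the design names.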

How the results depend on the processing

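Several alternatives here were chosen only after the data were seen. Among them were the handling of the mirrored columns and of coding length, and leaving out a control. The correction for the 10 h control and the lists without chromosome IX were others. No tested result changed direction under these alternatives. Single arrays did differ in sign for 2 list medians, Gcn4 targets in the deletion (0.11 and -0.28) and ribosomal protein genes without doxycycline (0.14 and -0.44). Taking the second tagged column, which was not run, would turn the sign of nearly all values of that comparison, as 0.797% of the 3262 genes with both columns have the same sign in them. Counting each result once per alternative, 63 counts and correlations stayed and 59 moved, 281 values of named genes stayed and 11 moved, and tests of the 10 lists that passed stayed past the threshold 64 times and lost it 26 times. For the count of genes that passed in the deletion (main value 0), scaling gave 1, single arrays without the replicate block 197, arrays within the replicate block 999, 2-fold on both arrays 79 and 1.5-fold 518. In tet over own promoter (0) the values were 5 with scaling, 1 with a robust fit, 256 without and 856 with the replicate block, 1 with all available arrays, 0 to 1 without single replicates, 67 at 2-fold, 451 at 1.5-fold, 1 without the 4 h control and 5 without the 10 h control. In tet without over with doxycycline (1) they were 0 as deposited and 0 with a robust fit. They were 1015 without and 2056 with the replicate block, 0 with all 12 arrays and 0 to 2 without single replicates. The values were 231 at 2-fold and 1089 at 1.5-fold. Leaving out the tagged control gave 0, leaving out the 10 h control 95, and correcting for the 10 h control 149. The count was 0 with the mirrored columns averaged, with the dye-corrected tagged array or with length removed. The tagged control (0) gave 1 without and 4 with the replicate block. The 4 h control (0) gave 387 and 1014, 71 at 2-fold and 513 at 1.5-fold. The 10 h control (178) gave 28 with scaling, 867 and 1347, 104 with available arrays, 96 to 107 without single replicates, 781 at 1.5-fold, 10 with the mirrored columns averaged, 102 with the dye-corrected tagged array and 105 with length removed. Exp 1 always had the numerator in Cy5 and Exp 2 in Cy3, so the replicate block is also the dye order. A dye effect of each gene thus stays in the residual without the block and is taken out within it. The larger counts in both cases treat the 2 arrays of a comparison as replicates. This holds only if Exp 1 and Exp 2 came from separate RNA, and the labels do not settle this. Otherwise the cause was not tested. Lists that passed (10) numbered 9 to 16 without single replicates, 0 with an estimated correlation, 1 with fry, 10 with the mirrored columns averaged and 9 with the dye-corrected tagged array; with these 2 the stress genes without doxycycline lost the threshold (adjusted p = 0.389 and 0.0559). On the first array alone, glycolysis over the own promoter had an adjusted p of 0.167, ribosomal protein genes without doxycycline 0.374 and NAD genes 0.0704. The correlation of the 2 tet comparisons (0.78) was 0.72 by Spearman, 0.45 and 0.64 between arrays of unlike dye order and 0.75 with length removed; that of the deletion with tet over own promoter (0.35) was 0.11 and 0.20 between arrays of unlike dye order, and with tet without over with doxycycline (0.40) it was 0.0954 and 0.38, 0.32 with length removed and 0.41 without chromosome IX. Separate spots, correlations over genes that passed and 2-fold counts on both arrays of the tagged control were not run, as the data gave no such values. Signal over background was not analysed here.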

Other observations

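The tests in this part were chosen only after the results were seen. Across genes the deletion and the tet strain without over with doxycycline correlated positively, at 0.40, and this was examined in more ways than the 3 patterns weighed above; it was set aside from them after its values were seen. The value was 0.43 with the dye effect regressed out and 0.32 with the length trend removed, and the lowest of the 4 array pairings was 0.0954. The deletion also correlated with the doxycycline controls, at 0.40 for 4 h and 0.36 for 10 h, although they share no strain with it. No explanation is offered for this correlation.

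RPN1, YLR162W, MDS3, CYC8, YLR012C, SSN3 and SGE1 were at -1 or below in at least 4 of the 5 comparisons with paired arrays, and 0 genes were at 1 or above as often. Longer genes had lower ratios in the Hcm1 comparisons, with Spearman coefficients of -0.27 in the deletion and -0.21 and -0.24 in the tet comparisons. They were also lower after 10 h of doxycycline (-0.16). The trend was weaker on the second array. The first and second arrays gave -0.27 and -0.18 in the deletion and -0.26 and -0.09 over the own promoter. Without over with doxycycline they gave -0.34 and -0.10, and after 10 h -0.20 and -0.06. After 4 h the coefficient was -0.05, with -0.13 and 0.08 on the 2 arrays, and in the tagged comparison it was -0.55 in the first column and 0.54 in the second. Correcting the tet comparison, which has doxycycline below the line, by adding the 10 h control took HCM1 from 5.65 to 6.67. HCM1 stood at 1.02 in that control, and the corrected value was not tested. On chromosome IX the kinetochore genes went both ways in the deletion, DSN1 at -1.14 and NDC80 at 0.10. The genes named in this paragraph were chosen after their values were seen.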
